A study of Homo sapiens with 9 samples.

How the data were processed

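Total RNA was measured by sequencing in human blood eosinophils, white blood cells of the granulocyte lineage. Per the labels' protocols, the cells were isolated from whole blood by negative magnetic selection, reached a purity of 99% on stained cytospins and were cultured for 18 h. Ribosomal RNA was removed before library preparation. The 9 libraries fall into 3 groups of 3. The group called IL-5 here received IL-5 alone at 1 ng/mL. The group called E1 also received TNF-alpha at 15 ng/mL and IFN-gamma, whose label gives the number 15 with a misprinted unit. The group called E2 received IL-5 together with IL-4 at 10 ng/mL, GM-CSF at 10 ng/mL and IL-33 at 50 ng/mL. The labels number 3 donors, and each number occurs once in every group.

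The authors deposited 1 table of raw read counts, with 57500 Ensembl gene identifiers and 1 column per library, and no normalization had been applied. Per the submitters' processing notes, the reads passed through bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts, with Subread 1.5.2 and the GRCh38 genome also named. The strand setting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Counts of overlapping or antisense genes, and of genes with near-identical copies, are therefore uncertain. Among the named genes this concerns FCGR3B, the GBP genes, CYP4F3 and CYP4F12 in particular, which have close relatives. Total counts per library ran from 6055723 to 11983014, and the library next to the largest held 7171769. Columns were matched to samples by the group code and the donor number in their names.

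Gene symbols were taken from a table of Ensembl identifiers, which matched 56410 of the 57500, and from GENCODE release 29, which matched 56898 and also gave the GRCh38 positions and gene types. Genes on chromosome Y and XIST, TSIX and JPX (99 rows together) were left out of every test and table, because their level depends on the donor. Genes were kept by the filterByExpr rule of edgeR (a count of about 10 in a median-sized library and 15 in total), which left 18641. The genes below that rule held 0.798% of the counts.

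Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM size factors, robust quasi-likelihood dispersions and the quasi-likelihood test (2-sided). All 9 libraries entered 1 fit, so that the 3 groups shared an estimate of the spread. The model held the group and no donor term, since no source used here states that the submitters' own test had one. That fit ignores the pairing of donors, so the spread between donors stays in its standard errors and p values. Genes past a Benjamini-Hochberg FDR of 0.05 were called. Fold changes are given on the log2 scale with the standard error of the fit, and levels as CPM (the usual per-library count rate, here scaled by the TMM factors), as mean ± SD.

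Because the labels give each donor number in all 3 groups, the same fit with the donor as a block was planned as an alternative. The pairing comes from those labels. Deviations from the group means correlated at 0.55 to 0.691 in all 9 pairs of libraries with the same number, and at -0.533 to -0.182 between different numbers, so the numbers paired the libraries. The biological coefficient of variation was 0.307 without the block and 0.141 with it. No replicate libraries agreed within sampling noise, and the lowest chi-square per gene between any pair was 12.95.

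There were 36 gene lists fixed before the data were examined. Each was tested with camera in limma 3.58.1 on voom values (2-sided) at a preset inter-gene correlation of 0.01, with adjustment over the 36 lists of a contrast. The number of called members was counted with adjustment over all genes tested and again over the list alone. Camera with an estimated correlation, fry, RLE factors and the donor block were the alternatives. In E1 the estimated correlation was 0.00282 for the IFN-gamma response list and -0.0309 for the pyroptosis list, both below the preset. Yet their camera adjusted p rose, from 1.98e-34 to 0.000365 and from 0.00206 to 0.0812. A higher p with an estimated correlation thus does not by itself show correlation within a list.

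Genes are named by a rule also fixed before the data were examined. For each contrast it takes the 8 largest rises and the 8 largest falls among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. It adds up to 4 members of each list with the smallest p. Y-linked genes, XIST, immunoglobulin and T cell receptor segments, HLA-DRB genes, GSTM1, GSTT1, UGT2B17 and ERAP2 were left out of naming. Some other genes that meet the rule are not reported here. The granule genes LTF, ANXA3 and CHI3L1 in the closing part fall outside the rule and were chosen after their values were seen. Levels of marker lists were summed as CPM and compared by exact permutation tests (2-sided), in which 3 against 3 libraries cannot give a p below 0.1.

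The counts of changed genes were also computed with the donor block, DESeq2 1.42.0, limma voom, RLE factors, library totals as the only scaling, no filter, a filter of 50 counts in 3 libraries, only the groups compared, a log2 fold change of at least 1, an FDR of 0.01, and without each library or donor. In a fit without 1 library, a group of 2 shares the estimate of the spread with the other groups.

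The tests were tried on simulated counts for 17805 genes, made from the means, library sizes, donor differences and dispersions of these libraries. In each comparison 200 genes were changed. The genes of a further list were raised 2-fold in both comparisons, and calls of its members are left out of the shares below. The changed genes were drawn from those with a mean of at least 5 CPM with IL-5 alone, so the shares do not cover lower genes. The donor differences and dispersions came from the fit with the block, so a gain with the block was built in. For E1 against IL-5, 80% of genes changed 4-fold and 10% of those changed 2-fold were recovered without the block, with 0 false calls. With the block these shares were 100% and 76%, and 11.0% of the calls were false. For E2 against IL-5, the shares without the block were 84% and 14% with 0 false calls, and with the block 98% and 94% with 12.2% false calls. The blocked fit thus made more false calls in the simulation than its threshold of 0.05 states. The list raised 2-fold was called in both comparisons, and 0 of 35 unchanged lists were. Each gene was drawn on its own, so members of the simulated lists were not correlated. The real TNF and NF-kB list had an estimated correlation of 0.497 in E1. These simulated lists therefore cannot show how often correlated lists are called falsely at the preset correlation.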

Results

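RNA levels were measured in human blood eosinophils from 3 donors after 18 h with IL-5 alone, which keeps these cells alive, or with 1 of 2 added cytokine mixtures. The E1 mixture added TNF-alpha and IFN-gamma, and the E2 mixture added IL-4, GM-CSF and IL-33. The series names its aim as a comparison of type 1 and type 2 polarization. Each group held 3 libraries. Total counts were 11983014, 6996851 and 6469048 with IL-5 alone, 7171769, 7097093 and 7020143 in E1, and 6932495, 6055723 and 7031463 in E2. The leading principal component held 48.4% of the variance and set E1 apart from the other groups, and the next components, with 19% and 14.2%, separated the donors.

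With E1, the transcripts that rose most included interferon-induced chemokines and guanylate-binding proteins. For the 6 of these given here the means with IL-5 alone were 11.2 CPM or lower. CXCL10, a chemokine that attracts T cells (ENSG00000169245, chromosome 4, 76021117 to 76023497, GRCh38), went from 2.23 ± 2.04 to 2193 ± 62.4 CPM (SD, n = 3), a log2 fold change of 10.00 ± 0.74 (SE, adjusted p = 3.23e-05). GBP5, a guanylate-binding protein of host defence (ENSG00000154451, chromosome 1, 89258950 to 89272804), rose from 11.2 ± 5.65 to 7322 ± 1070 CPM (log2 fold change 9.37 ± 0.43, adjusted p = 2.02e-06). CXCL9 rose from 0.838 to 628.2 CPM, GBP1 from 8.32 to 5933 CPM and GBP4 from 11.1 to 3407 CPM. CXCL11, at 0 to 4 counts per library with IL-5 alone, reached 716 to 1249 counts. ETV7, a transcriptional repressor induced by interferon, rose by 8.40 ± 0.61 on the log2 scale.

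All 25 measured members of the IFN-gamma response list rose in E1, and the same 25 were called when adjusted over the list alone (camera adjusted p = 1.98e-34, and 0.000365 with an estimated correlation). WARS1, a tryptophan tRNA synthetase, rose by 4.44 ± 0.18 on the log2 scale, to 2745 ± 116 CPM. Of 24 type I interferon-stimulated antiviral genes, 23 rose and 0 fell (23 adjusted over the list alone, camera adjusted p = 5.05e-28, and 0.00497 with an estimated correlation). OAS1, IFIT2 and XAF1 had log2 fold changes of 6.52, 5.12 and 6.20.

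Of 21 measured TNF and NF-kB response genes, 18 rose and 0 fell (21 rose when adjusted over the list alone, camera adjusted p = 7.16e-15). That list's adjusted p was 0.131 with an estimated correlation. SOD2, the mitochondrial superoxide dismutase, rose from 160.2 ± 25.7 to 4622 ± 427 CPM, and ICAM1, an adhesion molecule for leukocytes, from 12.8 ± 2.46 to 439.4 ± 3.82 CPM. TNFAIP2 rose by 4.28 ± 0.28 and RELB by 3.98 ± 0.37 on the log2 scale.

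Antigen processing genes rose as well. In the MHC class I list 14 of 18 members rose and 0 fell (15 adjusted over the list alone, camera adjusted p = 4.13e-14, and 0.0243 with an estimated correlation). With both the donor block and an estimated correlation that adjusted p was 0.0716. The peptide transporter genes TAP1 and TAP2 rose by 3.64 ± 0.19 and 3.23 ± 0.18, and the immunoproteasome subunits PSMB10 and PSMB8 by 2.71 ± 0.15 and 2.62 ± 0.20. In the MHC class II list 9 of 15 rose and 0 fell (13 adjusted over the list alone, camera adjusted p = 2.26e-07), and its adjusted p was 0.124 with an estimated correlation. HLA-DRA rose from 557.5 ± 124 to 2254 ± 700 CPM, and the protease gene CTSS rose by 2.86 ± 0.27. B cells and monocytes carry MHC class II as well, and what such cells add to these rises was not tested. B cell markers summed to 84.5 ± 23.2 CPM with IL-5 alone and 138.3 ± 29.9 in E1, higher in 3 of 3 donors. Of 10 measured B cell markers 0 were called by edgeR without the block (0 adjusted over the list alone, camera adjusted p = 0.795). At an unadjusted p under 0.05 1 was higher, DESeq2 called 1 and limma voom 0, and 2 rose with the block. Of 10 measured monocyte markers 2 rose, CD14 and VCAN, and 2 fell, CSF1R and CPVL (2 and 2 adjusted over the list alone, camera adjusted p = 0.503). CD14 averaged 1.39 ± 0.51 and 7.32 ± 4.56 CPM, and VCAN 1.90 ± 0.99 and 8.90 ± 3.66. The CD14 call was lost without any IL-5 replicate or E1 replicate 1 or 2 (adjusted p 0.0556 to 0.109), and the CPVL call without IL-5 replicate 2 or 3 or E1 replicate 1 or 3 (0.072 to 0.0833). Of 13 T cell costimulation and checkpoint genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.281 with an estimated correlation). CD274, which encodes the inhibitory ligand PD-L1, rose from 3.47 ± 1.95 to 708.8 ± 95.3 CPM. PDCD1LG2, the gene of PD-L2, rose by 4.52 ± 0.41, and CD40 by 2.92 ± 0.50.

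Death and survival genes moved in the same comparison. Of 25 measured apoptosis and survival genes, 14 rose and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 2.84e-05), and the adjusted p was 0.131 with an estimated correlation. The death receptor gene FAS rose from 24.4 ± 3.67 to 303.4 ± 38.1 CPM, while the inhibitors CFLAR and XIAP rose by 1.54 ± 0.17 and 1.26 ± 0.12. In the pyroptosis and inflammasome list, 7 of 15 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00206), and 11 rose and 3 fell with the donor block. Its adjusted p was 0.0812 with an estimated correlation. CASP4, CASP1 and GSDMD, the pore-forming gasdermin D, rose by 3.57, 3.34 and 1.82 on the log2 scale. Of 23 pattern recognition receptor genes, 15 rose and 0 fell (17 adjusted over the list alone, camera adjusted p = 1.44e-09, and 0.00497 with an estimated correlation). TLR7 and TLR8, sensors of single-stranded RNA, rose by 4.03 ± 0.21 and 5.21 ± 0.37.

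Of 25 eosinophil identity genes, 12 fell in E1, 3 rose and 10 did not pass (12 and 3 adjusted over the list alone, camera adjusted p = 0.0014), and the adjusted p was 0.581 with an estimated correlation. PTGDR2, the prostaglandin D2 receptor, went from 338.9 ± 59.6 to 69.1 ± 26.5 CPM (log2 fold change -2.29 ± 0.34), and the transcription factor gene CEBPE fell by 1.65 on the log2 scale. VSTM1 had a log2 fold change of -2.66 ± 0.26. The member with the largest rise was IDO1, a tryptophan-degrading enzyme that also stands in the IFN-gamma list, at 90.9 ± 40.8 with IL-5 alone and 4583 ± 1250 CPM in E1. Of 5 measured granule protein genes 0 passed the edgeR test without the block, and 0 adjusted over the list alone (camera adjusted p = 0.503). At an unadjusted p under 0.05 1 was lower, as it was by DESeq2 and by limma voom, and with the block 3 fell and 1 rose. CLC, the gene of galectin-10, came closest, at -1.05 ± 0.33 (adjusted p = 0.0507, and 0.0435 with the block).

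Among the genes that fell in E1 were CAMP, CYP4F3, CYP4F12, CRISP3, SULT1B1 and SEPTIN5. CAMP, the gene of the antimicrobial peptide cathelicidin (ENSG00000164047, chromosome 3, 48223347 to 48225491), went from 462.3 ± 395 to 2.67 ± 1.89 CPM (log2 fold change -7.42 ± 1.47, adjusted p = 0.00806). CYP4F3, which degrades leukotriene B4, had a log2 fold change of -5.24 ± 1.31 and CRISP3 one of -4.54 ± 1.23. The CYP4F3 call was lost without IL-5 replicate 1 or 2 or E1 replicate 2 or 3 (adjusted p 0.0568 to 0.0902). The CRISP3 call was lost without IL-5 replicate 1 or 2, any E1 replicate or E2 replicate 2 (adjusted p 0.0566 to 0.106). CAMP and CRISP3 are abundant in neutrophil precursors. Beside them, the 13 fixed neutrophil markers summed to 797.8 ± 110 CPM with IL-5 alone and 336.2 ± 31.2 in E1 (exact permutation p = 0.1, the smallest possible with 3 against 3). Markers of T cells summed to 23.9 ± 4.93 and 32.5 ± 3.10 CPM, and for these and the B cell sums the exact permutation p was 0.1 as well. Scaled by library totals, the T cell means were closer, at 25.59 and 28.73 CPM. In the neutrophil list 4 of 13 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.0635), and 10 fell and 2 rose with the block (0.00345, and adjusted p = 0.0977 with the block and an estimated correlation). CXCR2 had a log2 fold change of -3.19 ± 0.45, whereas FCGR3B had one of 1.76 ± 0.24.

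In all, 3813 of 18641 genes changed between E1 and IL-5 (2138 higher, 1675 lower) by edgeR's quasi-likelihood test, 2793 of them by 2-fold or more. With the donor block 7144 changed (3640 higher, 3504 lower), and 3807 of the 3813 kept their call and direction. Library totals as the only scaling gave 5096 genes, of which 31.1% were higher, against 56.1% with TMM, and it moved the median of all genes to -0.299 on the log2 scale. Without a filter 48.2% of 4357 genes were higher.

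**Figure D1:**
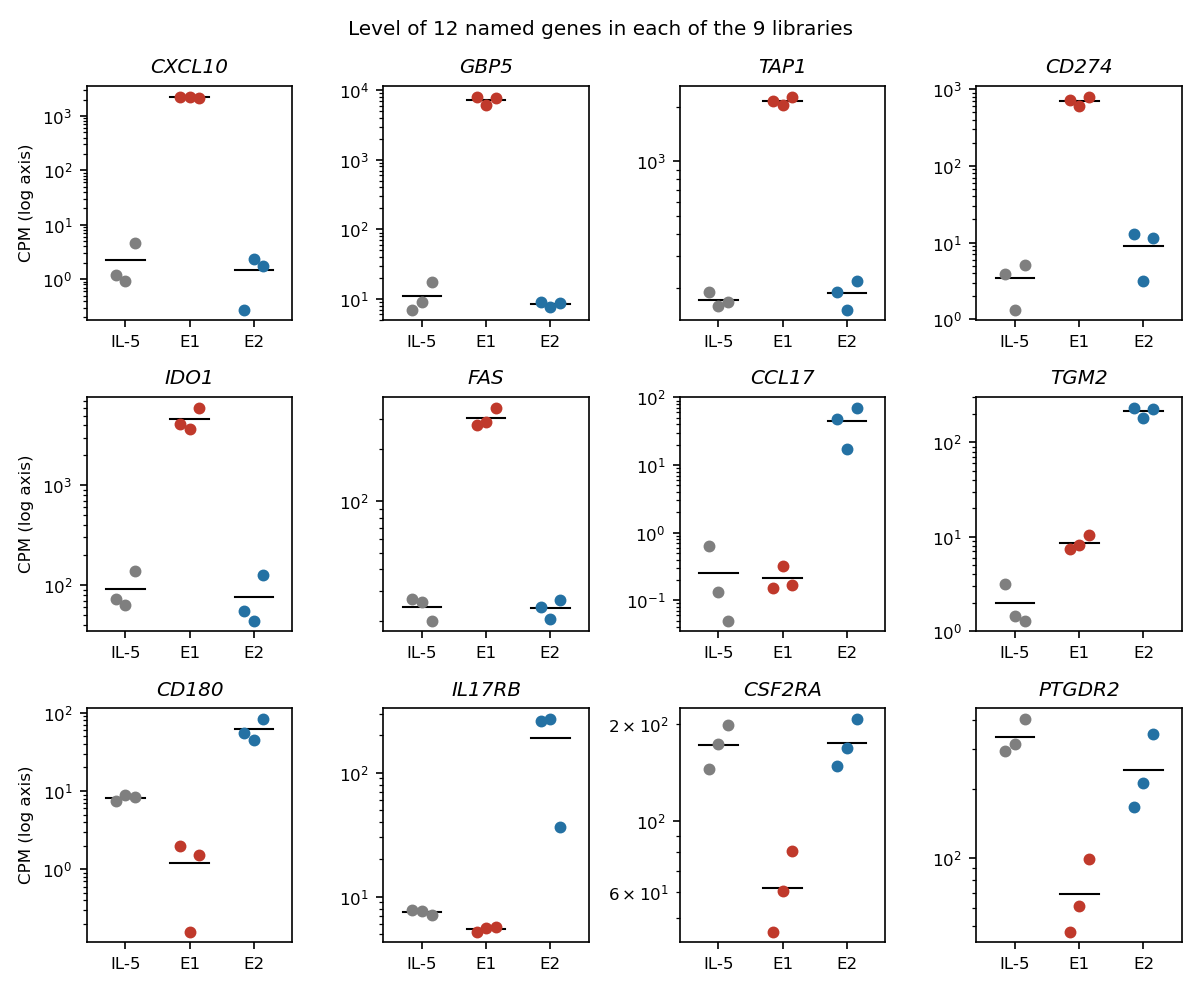
Each point is 1 library, with the group on the horizontal axis and the level in CPM on a log axis, and each black line is the mean of 3 libraries. A library with 0 counts is drawn at 0.05. CXCL10, GBP5, TAP1, CD274, IDO1 and FAS are highest in E1, where CXCL10 averages 2193 CPM, CCL17, TGM2, CD180 and IL17RB are highest in E2, where TGM2 averages 213.2 CPM, and CSF2RA and PTGDR2 are lowest in E1.

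With E2, the genes that rose most included TGM2, CCL17 and MAOA, the 3 members called in the fixed list of IL-4 and STAT6 targets. TGM2, a protein cross-linking transglutaminase (ENSG00000198959, chromosome 20, 38127387 to 38166578), went from 1.97 ± 1.03 to 213.2 ± 27.0 CPM (SD, n = 3), a log2 fold change of 6.68 ± 0.34 (SE, adjusted p = 6.62e-05). CCL17, a chemokine that attracts type 2 helper T cells (ENSG00000102970, chromosome 16, 57404767 to 57416062), stood at 0 to 8 counts per library with IL-5 alone and at 110 to 491 in E2 (adjusted p = 0.0157). The complement gene C3 rose from 7.62 ± 2.05 to 229.7 ± 200 CPM, and MAOA, which oxidizes amines, by 4.38 ± 0.65. POU2F2, CD180 and CD36 rose by 3.13, 2.91 and 2.82 on the log2 scale. The 5 falls that met the naming rule were FCGR3B (-2.15 ± 0.26), PTH2R, CCDC125, TRIM22 and PTGER4 (-1.31 ± 0.20).

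Of 17 measured IL-4 and STAT6 targets, 3 rose and 0 fell (10 rose when adjusted over the list alone, and 13 rose with the donor block). The camera adjusted p of the list was 2.01e-10, and it was 0.0445 with an estimated correlation, and 0.0974 with an estimated correlation and the block. MRC1, the mannose receptor, had a log2 fold change of 2.34 ± 0.42 (adjusted p = 0.0842 over all genes, 0.00109 over the list alone, and 0.00113 with the block). Of 22 STAT5 targets of IL-5 and GM-CSF signalling, 3 rose and 0 fell (10 adjusted over the list alone, 10 with the block, camera adjusted p = 1.48e-09), with an adjusted p of 0.171 with an estimated correlation. The members called were PIM3 (2.16 ± 0.23), IL2RG (1.60 ± 0.21) and DUSP6 (1.70 ± 0.25). These rises were not all particular to E2. In E1, PIM3 rose by 3.123 ± 0.235 and IL2RG by 2.795 ± 0.216. Of the same 22 targets 7 rose in E1 and 3 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.161).

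In the TNF and NF-kB list 1 of 21 members, ICAM1, rose with E2 (14 adjusted over the list alone, 11 with the block, camera adjusted p = 8.24e-12), and its adjusted p was 0.353 with an estimated correlation. ICAM1 rose from 12.8 ± 2.46 to 75.01 ± 35.3 CPM. NFKB2 and RELB had log2 fold changes of 2.61 ± 0.44 and 2.02 ± 0.35 (adjusted p = 0.076 and 0.0781 over all genes, both 0.0015 over the list alone, and 0.037 and 0.00415 with the block). Of 17 chemokines, 1 rose (9 adjusted over the list alone, 8 with the block, camera adjusted p = 8.32e-06, and adjusted p = 0.353 with an estimated correlation). CCL2 averaged 22.1 ± 13.2 CPM with IL-5 alone and 381.0 ± 338 CPM in E2, with an adjusted p of 0.123 over all genes, 0.00808 over the list alone, and 9.3e-05 with the block. IL17RB, the receptor of IL-25, averaged 7.58 ± 0.38 and 189.5 ± 133 CPM (adjusted p = 0.0525, and 0.0288 with the block). IL13, a type 2 cytokine, reached 3.57 ± 1.38 CPM from 0.428 ± 0.386 (adjusted p = 0.219, and 0.00309 with the block).

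Of 24 type I interferon-stimulated antiviral genes 0 were called in E2 by edgeR without the block, and the list was lower by camera (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.00232). At an unadjusted p under 0.05 4 were lower and 1 higher, DESeq2 called 2 lower and 1 higher, and limma voom 0. Its adjusted p was 0.353 with an estimated correlation, and the list call was lost without IL-5 replicate 1 (adjusted p = 0.0986). With the block 4 members fell and 1 rose. IFIT2 and OASL had log2 fold changes of -1.46 ± 0.26 and -1.60 ± 0.36 (adjusted p = 0.00142 and 0.000247 with the block). Of the 25 IFN-gamma response genes 0 were called by edgeR without the block (1 rose adjusted over the list alone, camera adjusted p = 0.243), 3 were higher at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0, and 4 rose and 1 fell with the block. Of 25 eosinophil identity genes 0 were called by edgeR without the block (0 adjusted over the list alone, camera adjusted p = 0.0931, 0.0103 with the block, and adjusted p = 0.247 with the block and an estimated correlation), 2 were lower at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0, and 6 fell and 2 rose with the block. IL5RA, the IL-5 receptor, averaged 215.0 ± 69.3 CPM with IL-5 alone and 76.8 ± 56.0 in E2 (adjusted p = 0.436, and 0.0191 with the block).

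In all, 33 of 18641 genes changed between E2 and IL-5 (27 higher, 6 lower) by edgeR's quasi-likelihood test without the donor block, and each differed by 2-fold or more. This count depended on the tool, with 503 by DESeq2 and 12 by limma voom. At an unadjusted p under 0.05 there were 2234. With the donor block 2104 genes changed (1194 higher, 910 lower), and all 33 were among them in the same direction. The blocked count was 862 to 2179 without 1 library. In the fit without the block the count was 1 without any 1 of the 3 IL-5 libraries, and TGM2 was the gene that remained. That count was 10, 11 and 7 without E1 replicates 1, 2 and 3, 14 without E2 replicate 1 and 119 without E2 replicate 2.

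**Figure D2:**
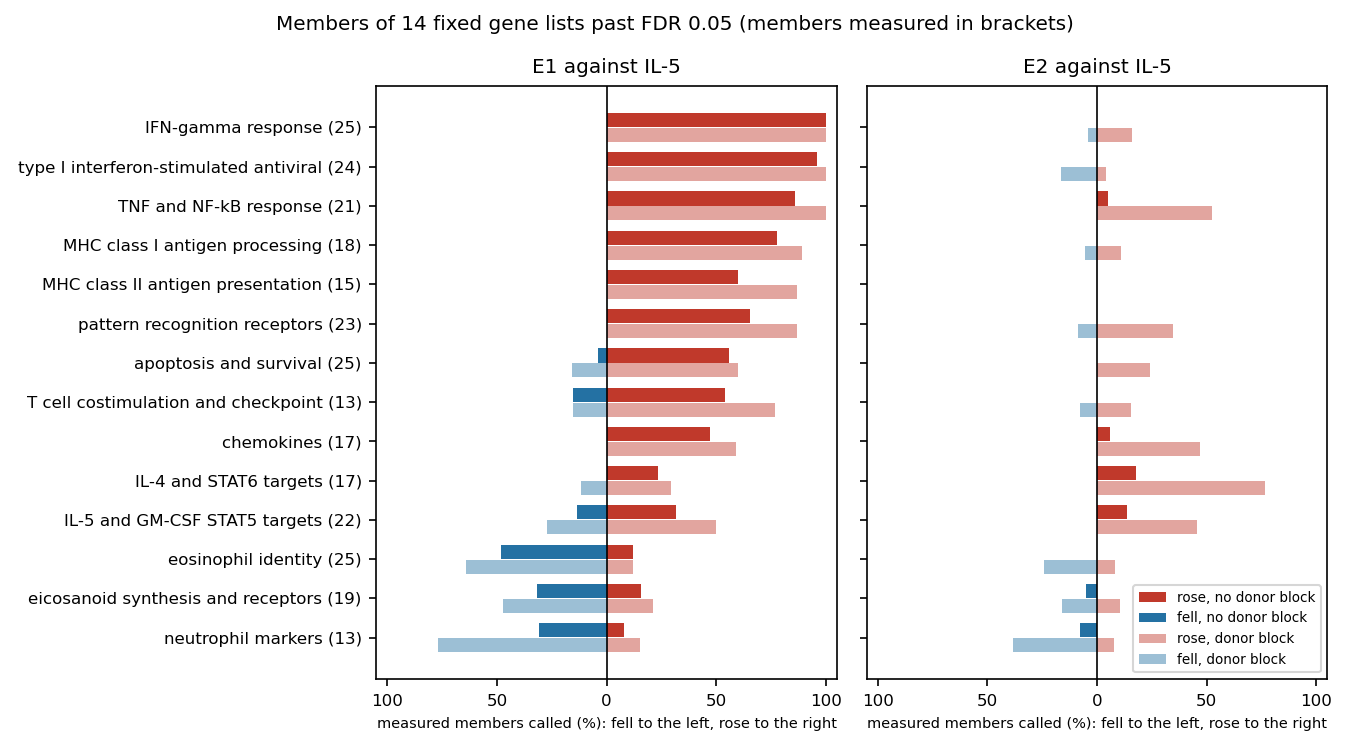
For 14 of the fixed lists, bars give the share of measured members (in percent, with the number measured in brackets) that rose (red, to the right) or fell (blue, to the left) at an FDR of 0.05. Dark bars are the fit without the donor block and pale bars the fit with it. All 25 IFN-gamma response members rose in E1, and 13 of 17 IL-4 and STAT6 targets rose in E2 with the block.

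The direct comparison of E1 with E2 tests the difference between both mixtures. All 25 IFN-gamma response genes and 23 of 24 antiviral genes were higher in E1 (camera adjusted p = 9.04e-38 and 3.27e-32, and 0.000269 and 0.00272 with an estimated correlation; 25 and 23 adjusted over the list alone). CXCL10, CXCL9 and GBP5 were higher in E1 by 10.58 ± 0.77, 10.16 ± 0.40 and 9.74 ± 0.44 on the log2 scale. Of 21 TNF and NF-kB genes 12 were higher in E1 and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 1.73e-09, and adjusted p = 0.316 with an estimated correlation), with ICAM1 at 2.55 ± 0.30. FAS, CD274 and TLR8 were higher in E1 by 3.67 ± 0.18, 6.27 ± 0.59 and 6.25 ± 0.41. FCGR3B was higher in E1 by 3.91 ± 0.27.

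Among the genes lower in E1 than in E2 were CCL17, CAMP, CD180, IL17RB, TGM2, MAOA, RRS1 and CYP4F12. TGM2 averaged 8.66 ± 1.51 CPM in E1 and 213.2 ± 27.0 in E2, and CD180 held 1 to 13 counts per library in E1 and 290 to 583 in E2. The CAMP call was lost without any E1 replicate and without E2 replicate 1 or 2 (adjusted p 0.0511 to 0.0745). Of 17 IL-4 and STAT6 targets, 7 were lower in E1 and 3 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.0277, and adjusted p = 0.32 with an estimated correlation). This list call was lost without E1 replicate 2 (adjusted p = 0.053) and without E1 replicate 3 (0.0565). Of 10 type 2 cytokine and alarmin genes, 3 were lower in E1 and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.315). IL13 had a log2 fold change of -3.68 ± 0.97 and the IL-33 co-receptor gene IL1RAP one of -1.37 ± 0.29, whereas IL13RA1 was higher by 1.51 ± 0.22. The IL13 call was lost without E1 replicate 2 or 3 or E2 replicate 1 or 3 (adjusted p 0.0646 to 0.0883). PECAM1 and BCL2, a survival gene, were lower in E1 at -3.03 ± 0.46 and -2.37 ± 0.45, and CSF2RA, the GM-CSF receptor, at -1.49 ± 0.23.

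In all, 3055 genes differed between E1 and E2 (1821 higher in E1, 1234 lower), and 6294 with the donor block (3125 higher, 3169 lower), among them 3052 of the 3055 in the same direction. Library totals as the only scaling gave 4035 genes with 36.2% higher, against 59.6% with TMM, and a median of all genes of -0.268.

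Both mixtures were compared with the same IL-5 libraries. Of the genes called for each, 18 rose with both and 3 fell with both, where independent lists would share 3.10 and 0.539. With the donor block 596 rose and 588 fell with both, where independent lists would share 233.2 and 171.1, and 102 rose in E1 and fell in E2 while 82 did the opposite. The log2 fold changes correlated across genes at 0.362 (genes are not independent replicates), with a covariance of 0.234. In 20 simulations of unchanged groups against such controls the mean correlation was 0.485 and the mean covariance 0.0969, so the covariance exceeded the simulated one by 0.137. These simulations drew the libraries independently, whereas the real ones share donors, so their values are not a matched reference. With the block the observed covariance was 0.238 and the simulated one 0.0355, while the observed correlation of 0.369 was below the simulated 0.467. In the simulations with the block 0.15 genes on average were called higher and 0.25 lower with both mixtures. Only 0.9 genes for E1 and 1.1 for E2 were called higher at all, so these overlaps are no reference for 596 and 588. The 0.15 still exceeds the 6.19e-05 of independent lists. The shared IL-5 libraries alone thus raise an overlap above independence, so part of the observed excess may come from them. The 3 control libraries are too few to be split. The correlation was 0.20 without E2 replicate 1. The shared genes numbered 1 without any 1 of the IL-5 libraries, 7, 8 and 6 without E1 replicates 1, 2 and 3, 12 without E2 replicate 1 and 90 without E2 replicate 2.

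**Figure D3:**
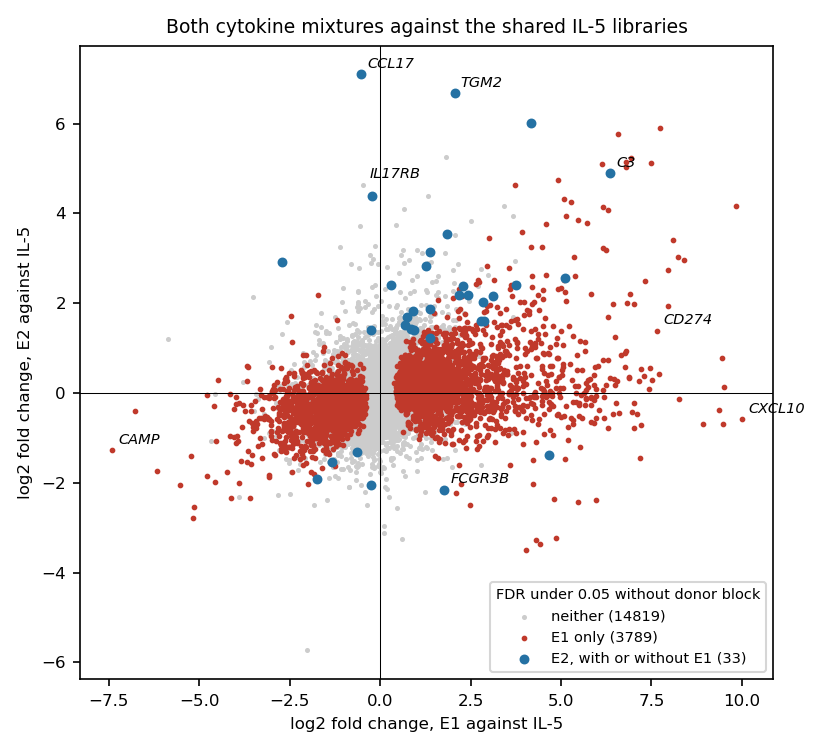
Each point is 1 of 18641 genes, with its log2 fold change in E1 against IL-5 on the horizontal axis and in E2 against IL-5 on the vertical axis. Blue points are the 33 genes called in E2, red points the 3789 called in E1 only and grey points the 14819 called in neither, all without the donor block. CXCL10 lies far to the right near the horizontal line, and TGM2 and CCL17 lie at the top.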

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

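Tests with the donor (replicate) block combined with another choice (except leaving out a donor), thinning, the removal of small structured RNAs or marker genes, the list tests without single libraries and the marker sums within donors were chosen after the data were seen. No named gene and no list was called in the opposite direction under any alternative run on it. The NK cell marker list in E1 and the NADPH oxidase list between E1 and E2, not called with or without the block, turned direction with it.

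For E1 against IL-5 the 3813 calls stayed within 1.5 times under DESeq2 (4276), limma voom, RLE factors, both filters, library totals and the other settings not named next. The replicate block gave 7144 genes, and 5929 with DESeq2, 7196 with RLE, 6845 after thinning, 7125 without small structured RNAs and 7353 with the GC and length trend removed. An FDR of 0.01 gave 2045. Leaving out 1 library gave 2637 to 3869 genes, and 5641 to 7524 with the block. Leaving out a donor gave 1883 to 2297, and 5127 to 5823 with the block.

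For E2 against IL-5 the 33 calls became 2104 with the replicate block, 503 with DESeq2, 12 with limma voom, 618 without a filter, 3 with only the groups compared and 1 at an FDR of 0.01. With the block there were 1745 by DESeq2, 2143 with RLE, 676 at a log2 fold change of 1 or more, 1996 after thinning, 2162 without small structured RNAs and 2165 with the trend removed. Leaving out 1 library gave 1 to 119 genes, and 862 to 2179 with the block (1181, 862 and 1087 without IL-5 replicates 1, 2 and 3, 962 and 1369 without E2 replicates 1 and 3). Leaving out a donor gave 1 to 6, and 698 to 1150 with the block.

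For E1 against E2 the 3055 calls became 6294 with the replicate block, and with it 5199 by DESeq2, 6331 with RLE, 6036 after thinning, 6267 without small structured RNAs and 6437 with the trend removed. An FDR of 0.01 gave 1620. Leaving out 1 library gave 2081 to 2992, and 5070 to 6447 with the block. Leaving out a donor gave 1399 to 1703, and 4389 to 5033 with the block. A stricter FDR lowers a count by construction, and the block removes the spread between donors. For the other settings, libraries left out included, the cause was not tested.

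The correlation of the E1 and E2 effects against IL-5 was 0.369 with the replicate block and 0.20 to 0.504 without 1 library. The 21 genes changed the same way in E1 and E2 against IL-5 became 1184 with the replicate block and 1 to 90 without 1 library.

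Of the named genes called, 4 of 75 in E1, 16 of 17 in E2 and 3 of 37 between E1 and E2 lost their call without some library. These losses were counted without the block. PTGER4 lost its E2 call with RLE factors. With the block kept, leaving out 1 library still called 29 to 33 of all 33 E2 genes. The block ended none of the calls of named genes, and it added 4 of 5 and 22 of 25 named genes not called for E1 and E2. Of 15, 10 and 14 lists called for E1, E2 and E1 against E2, 4, 1 and 5 held with an estimated correlation. With fry 13, 1 and 11 held, and 5, 0 and 3 lists were gained. The block kept all of them with the preset correlation and added 1, 4 and 1. With the block and an estimated correlation 3, 0 and 3 held, none of them a list the block gained. The p rose even for lists whose estimate was below the preset correlation. Losses with an estimated correlation thus do not by themselves show correlation within the lists. The lists gained with the block were neutrophil markers for E1, cytokines and growth factors, eosinophil identity, cholesterol and neutrophil markers for E2, and granule proteins between E1 and E2. The replicate block changed no other call. Of 30 marker levels, 28 moved by less than 1 SD when scaled by library totals. Depth limits the genes at a few counts, such as CXCL11 and CCL17 with IL-5 alone.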

Other observations

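The tests on granule transcripts, depth, GC content and marker sums within donors in this part were chosen only after the results were seen. Lipid mediator genes changed in E1 in either direction. Of 19 eicosanoid genes, 6 fell and 3 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.256). LTC4S, which makes leukotriene C4, had a log2 fold change of -2.57 ± 0.32, whereas PTGS2, the inducible cyclooxygenase, rose by 2.52 ± 0.43 and the prostaglandin E2 receptor gene PTGER2 by 2.38 ± 0.35. Among 16 receptors and kinases of the added cytokines, 7 rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.103). JAK3 and JAK2 rose by 4.89 ± 0.32 and 2.20 ± 0.22, the IFN-gamma receptor gene IFNGR2 by 1.99 ± 0.27, and CSF2RA had a log2 fold change of -1.47 ± 0.23. IL1RL1, the IL-33 receptor, was at -1.54 ± 0.68 (adjusted p = 0.161, and 0.0114 with the donor block). Of 18 cholesterol genes 5 rose in E1 (6 adjusted over the list alone, 11 with the block, camera adjusted p = 0.0158, and adjusted p = 0.581 with an estimated correlation), and this list call was lost without E1 replicate 2 (adjusted p = 0.165). SQLE and HMGCS1 rose by 1.58 ± 0.32 and 1.22 ± 0.22.

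Of 17 chemokines 8 rose in E1 and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.000738, and adjusted p = 0.361 with an estimated correlation). Of 22 cytokines and growth factors 12 rose and 3 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.124 with an estimated correlation). TNFSF13B, the B cell survival factor BAFF, rose by 3.67 ± 0.25 and the cytokine subunit gene EBI3 by 4.85 ± 0.44, whereas IL16 had a log2 fold change of -2.19 ± 0.20. Of 19 immediate early and heat shock genes 7 rose in E1 and 1 fell (9 and 1 adjusted over the list alone, 12 and 1 with the block, camera adjusted p = 0.00186, and adjusted p = 0.427 with an estimated correlation). Of 19 unfolded protein and stress response genes 4 rose (4 adjusted over the list alone, 6 with the block, camera adjusted p = 0.0105, and adjusted p = 0.124 with an estimated correlation). For 17 IL-4 and STAT6 targets in E1 the median log2 fold change was -0.136 and the mean 0.32, and the direction by camera was up (4 rose, 4 adjusted over the list alone, adjusted p = 0.449).

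Of 24 oxidative phosphorylation genes 0 were called in E2 by edgeR without the block, 3 rose adjusted over the list alone and 8 rose with the block (camera adjusted p = 2.92e-09, and adjusted p = 0.496 with an estimated correlation). At an unadjusted p under 0.05 9 were higher, and DESeq2 called 2 and limma voom 0. CYCS and COX6C had log2 fold changes of 1.01 ± 0.19 and 0.81 ± 0.16 (adjusted p = 0.00079 and 0.00469 with the block). The long nuclear RNA NEAT1 rose in E1 from 1104 ± 236 to 3186 ± 343 CPM. The libraries held 30754 to 45581 genes with at least 1 count. In E1, at like depth (7020143 to 7171769 counts), they held 31705 to 40620, and the highest number in each group came from the same replicate number. Genomic DNA or unspliced RNA may add such genes, which these counts cannot test. Small structured RNAs took 3.80 to 9.74% of the counts.

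With IL-5 alone, NK cell markers summed to 40.7 ± 16.7 CPM, platelet markers to 37.9 ± 7.40, erythroid markers to 39.9 ± 13.8 and basophil markers to 198.4 to 391.1 CPM. Monocyte markers summed to 3672 ± 2910 CPM, of which LYZ, which neutrophil precursors also make, held 3407 ± 2730. The exact permutation p of these sums for E1 against IL-5 ran from 0.2 to 0.8, where 0.1 is the smallest that 3 against 3 can give, and that test ignores the pairing. Within donors, the NK cell and platelet sums, like those of T and B cells, were higher in E1 than with IL-5 alone in 3 of 3 donors, and the basophil, erythroid and monocyte sums in 1 of 3. Some of this depended on the TMM scaling. Scaled by library totals, donor 3 was lower in E1 for T cells (27.52 with IL-5 alone, 26.78 in E1), platelets (50.08 and 45.73) and basophils (214.3 and 192.3). The erythroid sum of donor 2 was then level (30.44 and 30.43). In E2 the NK cell, B cell, basophil and platelet sums were higher in 3 of 3, the T cell and erythroid sums in 2 of 3 and the neutrophil and monocyte sums in 0 of 3. Neutrophil markers averaged 563.6 ± 146 CPM in E2, B cell markers 146.8 (60.92 to 257.6) and erythroid markers 86.7 ± 74.4, and the permutation p of the 8 sums for E2 ran from 0.2 to 0.8. A paired exact test on 3 donors cannot give a p below 0.25.

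Transcripts of neutrophil granules, in 2 lists assembled after the data were seen, differed up to 16.4-fold (secondary granule) and 31.4-fold (primary granule) among the 3 donors with IL-5 alone, while the fixed neutrophil marker sum differed up to 1.32-fold. LTF, the most abundant of those quoted here, averaged 2224 CPM with IL-5 alone, and 1 of the 26 members also stands in an eosinophil list. In E1, 21 of 26 measured members fell, 1 rose and 4 did not pass with the donor block, with a median log2 fold change of -2.14. Whether contaminating neutrophil-lineage cells remained after the magnetic isolation was not tested. Loss of 1 kind of such cell, if it alone made these transcripts, would lower all of them alike. For 15 of 26 the 95% interval left out that median. CAMP was at -7.29 (-7.82 to -6.76), LTF at -0.95 (-1.30 to -0.59), ANXA3 at -0.04 (-0.36 to 0.28) and CHI3L1 at 0.60 (0.21 to 1.00). These values argue against such a uniform loss as the whole cause. Loss of a mix of cells with different granule transcripts need not lower all alike, nor need any loss if eosinophils make some members. No such profile was measured, so the values cannot decide on a loss of that kind. A scaling factor per library would also move all of them alike, so the same 15 of 26 argue against scaling as the whole cause. A change of transcription or RNA stability in E1, cell loss that is partial or uneven, or both may remain, and neither was tested further.

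The step from 33 to 2104 E2 genes with the donor block was set against technical trends. Removing a trend with GC content and gene length, with the block kept, left 93.3% of the calls in the same direction, and thinning all libraries to the smallest left 1996 calls, so neither trend nor depth accounts for the step as the whole cause. E2 ratios correlated between donors at 0.408 to 0.498 across genes, and E1 ratios at 0.826 to 0.847. With the block the biological coefficient of variation fell from 0.307 to 0.141. Recovery of simulated 2-fold changes rose from 14 to 94%, with 12.2% of the calls outside the raised list false. The simulation held the donor differences of the fit with the block, so that gain was built in and is no evidence. The correlation of E2 ratios between donors is what an E2 response hidden by donor spread would give. The lower coefficient follows from differences between donors, with or without such a response. The simulated share of false calls rests on few changed genes and on the blocked model itself. It cannot be carried over to the 2104 calls. The number of calls was not stable. With the block kept, it was 862 to 2179 without 1 library and 698 to 1150 without a donor. Whether a different mix of cells in E2 adds to the calls was not tested.

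Splitting the 6 libraries of each comparison in the 10 possible ways gave the count of the real split in 1 of 10 cases, with 3813, 33 and 3055 genes for E1 against IL-5, E2 against IL-5 and E1 against E2, and a highest count of 0 in the other splits. The other splits include 3 that part all 3 donor pairs as the real one does, and these gave 0 calls with the donor block as well. Every other split mixes libraries of both groups, so real changes between the groups enter its spread. The 0 calls there therefore say little about the rate of false calls. With 10 splits the share cannot fall below 0.1, so the splits are too few for a share under 0.05.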
